A study of Triticum aestivum with 3 samples.

How the data were processed

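Leaves of wheat (Triticum aestivum) seedlings were sampled after 2 days of treatment, and their degradomes were sequenced in 3 treatments, an untreated control, dithiothreitol (DTT) and DTT with tauroursodeoxycholic acid (TUDCA). Per the labels, each treatment had 3 independent biological replicates, 9 leaf samples in all. A degradome library holds the 5′ ends of RNA fragments that carry a 5′ monophosphate, which is what slicing of a transcript by a small RNA leaves on the downstream fragment. Whether the reads reported below arose by slicing, or changed with the amount of transcript, was not tested. The data used here hold no cleavage position, category or transcript abundance. Per the labels, about 20 µg of total RNA with a RIN above 7.0 went into each library, of which 150 ng was poly(A)+ RNA, and the first 36 nt of each insert were read from 1 end on an Illumina HiSeq.

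The deposited data are 3 tables, 1 for each pair of treatments, with a line for each pair of a small RNA and a transcript. Per the file headers, each line gives raw degradome read counts in each of the 6 libraries compared, and a second read number called normalized. The values show that this deposited second number is an expected count, the raw count divided by a number of at least 1 (often a small whole number), so the authors appear to have shared reads over the places they map to, a reading that no header states. It served here to recover the library reads and, through TPB, in 1 alternative test, while the main test used the raw counts. The authors' signal per library, headed TPB, equals that second number multiplied by 1 factor per library, and each factor is a fixed constant over a whole number between 11253643 and 13006162, within a tolerance of 0.001. That whole number was taken as the library's reads, although the headers do not say whether it counts raw, filtered or mapped reads. The deposited log2 ratio equals the log2 of the ratio of mean TPB in every line that has one, and a dash stands where 1 of the means is 0. The read mapper, transcript set, target caller and its thresholds are not given in the sources used here, and the tables used here hold no position, category, alignment score, p-value, transcript annotation or abundance of the small RNAs themselves. A pair is listed in a table exactly when it has reads in at least 1 of the 2 treatments compared. No listed column of per-sample values was left unused.

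Many lines hold the same reads, because related small RNAs and homeologous transcripts are listed separately. Lines that share a small RNA or a transcript, and whose raw counts over the 9 libraries differ in sum by at most 20% of the larger line's reads, were therefore linked and merged into 1 degradome signal, represented by its line with the most reads. Merged lines can belong to more than 1 small RNA family. This gave 4574 signals from 12450 pairs of small RNA and transcript, and 3 pairs listed more than once in a table were left out. The merging rule, the filter and the normalization were set after the tables had been read. A version merging at 5%, with TMM scaling and with all 3 treatments in 1 fit, had been run and its calls seen when 20% was chosen, because near-copies of 1 signal were still being counted apart. The counts under 5% stand beside the main ones for that reason.

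The design written before the data were examined had expected 1 library per treatment and cleavage positions with categories. It named a count test in case replicates were given, and a signal takes the place of a position here. Raw counts of the signals were tested with edgeR 4.0.16 (quasi-likelihood, R 4.3.3), in a fit of the 2 treatments compared, with the library reads as library sizes and no further scaling. Signals entered a test when they passed edgeR's expression filter with a minimum count of 5 and a minimum total of 10. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05. On simulated counts with 45 changed signals in each of 20 sets, the test of DTT against control called 16% of the changes of 2-fold, 55.3% of 4-fold and 87.7% of 8-fold among 156 signals. For DTT with TUDCA against control these shares were 23%, 73.7% and 98.3% of 166 signals, and against DTT 11.7%, 58% and 95% of 187. Between 0.5% and 0.7% of unchanged signals were called. The 45 changed signals are more than were called in any comparison of the data, which makes the Benjamini-Hochberg cutoff easier to pass. Counts were also drawn from the trend of the dispersion, with no spread of its own for each signal. The shares may therefore overstate what the tests could find.

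The 25 lists of conserved microRNA families were fixed before the data were examined, each paired with its usual target class, and signals were assigned by the family number in the small RNA's name. Names such as zma-MIR164h-p5_2ss4CG17CG_1 thus stayed in the family of their number. No source used here shows that such small RNAs share the family's targets, so target classes below describe families, not signals. For each list the reads of all signals were summed per library and the sums tested together in edgeR. This test of sums was added after the tables had been read. The median fold change of a list with at least 3 tested members was also placed among 10000 random lists of like abundance. The 10 lists of target annotations fixed beforehand (protein folding, cell death, redox and others) could not be used, because 0 of the 7483 transcript IDs matched the reference gene table and the tables do not pair IDs with names. Small RNAs are named as deposited, and chromosome arms are those written in the transcript IDs.

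The rule for named items, fixed beforehand, took for each comparison the 10 signals with the largest increase and the 10 with the largest decrease in log2((value + 1) / (value + 1)), with 1 signal per transcript and a larger value of at least 10, and up to 4 members of each list by abundance. The part of that rule on categories could not be applied. Every signal that passed the test is named too. The values of this rule, and of the counts of 2-fold differences, are mean reads scaled to the mean library size of the 9 libraries. All other values are given as reads per 10M library reads, mean ± SD over 3 libraries. With 3 libraries against 3, an exact two-sided permutation test cannot give a p below 0.1. A group with 0 reads is set at a floor of 3 counts, which is between 2.31 and 2.67 per 10M for 1 library, and a group with 1 to 3 reads is given as a ratio with its counting interval. These cover counting error only, since reads were not counted by molecular identifiers.

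Alternatives were the deposited scaling replaced by TMM or by centring each library on its median signal, DESeq2 1.42.0 with library-read or its own size factors, limma 3.58.1 on log2(TPB + 80), no filter or edgeR's default filter with a minimum count of 10 and a total of 15, 1 line per transcript, other merging rules, all treatments in 1 fit, replicate number as a block, and each library left out in turn. Calculations outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.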

Results

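Degradome libraries from wheat seedling leaves were compared between an untreated control, dithiothreitol (DTT) and DTT with tauroursodeoxycholic acid (TUDCA), with 3 independent biological replicates each. DTT reduces disulphide bonds and disturbs protein folding in the endoplasmic reticulum (ER), and TUDCA is a bile acid used as a chemical chaperone against ER stress. The study asked which transcripts are targeted by microRNAs involved in ER stress. The libraries held 12.1M ± 0.704M reads in the control, 12.7M ± 0.197M in DTT and 12.8M ± 0.236M in DTT with TUDCA (mean ± SD, n = 3), with a range from 11.25M to 13.01M. The tables paired 1233 small RNAs with 7483 transcripts, and 108 of the small RNAs carried wheat (tae) names, 1017 carried names from other species and 108 were named PC. After lines holding the same reads were merged, 4574 degradome signals with 55312 reads remained. Depth per signal was low, with 707 signals at 10 reads or more and 2818 (61.6%) at 3 reads or fewer over all 9 libraries.

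The signal with the most reads was that of PC-3p-103864_22, at 248 ± 52.2 reads per 10M library reads in the control, 239 ± 97.4 in DTT and 315 ± 52.4 in DTT with TUDCA. The family of miR160, which targets auxin response factors, gave the next strongest signals. The tae-miR160 signal on arms 1AL, 1BL and 1DL stood at 217 ± 18.5, 179 ± 81.4 and 296 ± 109, and that on 7AL, 7BL and 7DL at 127 ± 21.2, 126 ± 58.3 and 126 ± 50.9. Among other strong signals were tae-miR9676-5p, aly-miR169d-5p_L-1 (4AL), ath-miR847_L-2 (1DS), aly-MIR163-p5_2ss8GA18GC (7BS) and tae-miR167b_R+1_2ss9AC21AC (7AL, 7DL). The 10 strongest signals held 27.3% of all reads and the 100 strongest 55.8%. Signals of the 25 conserved families fixed beforehand held 40.5% of the reads.

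A control library showed 1190.3 ± 44.8 signals, a DTT library 1275 ± 159 and a library of DTT with TUDCA 1503.3 ± 83.0 (SD, n = 3). Reads in signals were 4452 ± 354, 4725.4 ± 954 and 5552.9 ± 420 per 10M. For both measures, every library of DTT with TUDCA lay above every control library, with an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. Against DTT, exact permutation p was 0.2 for both. For DTT against the control, exact permutation p was 0.6 for signals and 0.8 for reads. DTT replicate 3 was the lowest of all libraries on both, with 1117 signals and 3699.8 reads per 10M.

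**Figure D1:**
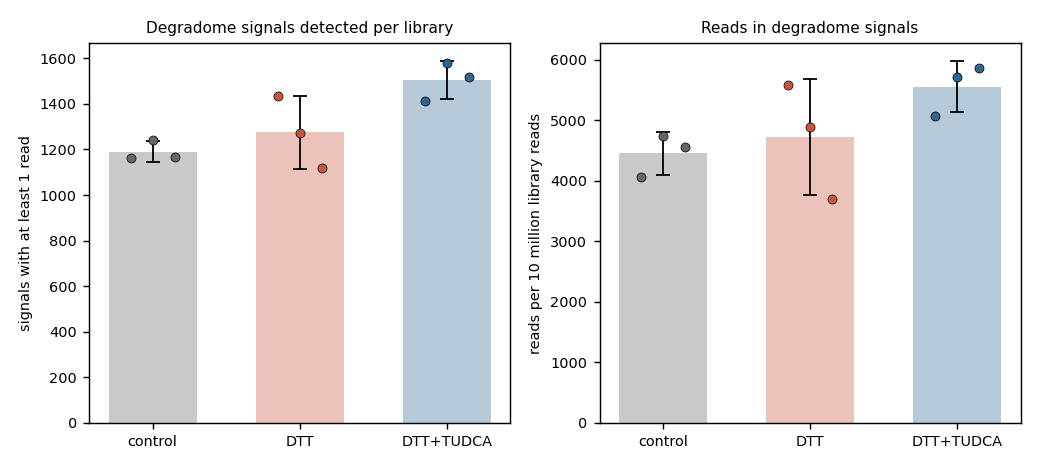
Degradome signals with at least 1 read (left) and reads in signals per 10M library reads (right) for each library, where points are libraries and bars are means with SD of 3 libraries. The 3 libraries of DTT with TUDCA hold 1414 to 1578 signals, above the 1163 to 1242 of the control, while the DTT libraries span 1117 to 1435.

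DTT was compared with the control to find degradome signals that change under the reductant. The signal of zma-MIR164h-p5_2ss4CG17CG_1 on a 6AL transcript rose from 25.0 ± 4.75 to 131.6 ± 73.9 reads per 10M. The miR164 family is known to target NAC transcription factors, but the 6AL transcript is not annotated here, so whether it is one is not known. The signal of aly-MIR163-p5_2ss8GA18GC (7BS) rose from 45.8 ± 7.98 to 141.5 ± 50.4, that of aly-MIR161-p5 (5BL) from 9.48 ± 2.20 to 30.3 ± 2.79, and that of aly-miR156a-5p_R+1_1ss20CT on a 3B transcript from 5.52 ± 0.779 to 20.4 ± 12.6. The miR156 family targets SPL transcription factors. A single signal fell, that of har-miR403a_R-3 (2AL, 2BL, 2DL), from 9.31 ± 5.55 to 1.05 ± 0.909. In each of these 5 signals the 3 DTT libraries all lay on 1 side of the 3 control libraries. The log2 fold changes were 2.39 (SE 0.48, adjusted p = 0.000212) for MIR164h, 1.67 (SE 0.48, adjusted p = 0.0381) for MIR161, 1.62 (SE 0.48, adjusted p = 0.0381) for MIR163, 1.86 (SE 0.56, adjusted p = 0.0402) for miR156a and -3.02 (SE 0.94, adjusted p = 0.0458) for miR403a. The edgeR test thus called 4 signals higher and 1 lower of 156 tested, with 26 at an unadjusted p under 0.05. With lines merged at 5% it called 6 and 1. The groups did not overlap in 34 signals (21.8%, where chance gives 10%). The median log2 fold change of all tested signals was -0.08 by library reads, 0.07 by TMM and 0.04 after median centring, and relative to the first of these the called changes were 2.46, 1.74, 1.70, 1.94 and -2.95. The split of higher and lower was 4 and 0 under TMM and 3 and 0 after centring, as miR403a was lost under both and miR156a after centring. Each of these calls was lost without at least 1 of the libraries, where the test also has fewer libraries. The counts were 0 and 0 without control replicate 1 or 3, 3 and 1 without control replicate 2, 2 and 3 without DTT replicate 1, 1 and 0 without DTT replicate 2, and 3 and 0 without DTT replicate 3. All 5 calls were lost by limma, and all but that of MIR164h also with 1 line per transcript, with every listed line and without a filter on low counts. DESeq2 with library reads ended those of MIR161, miR156a and miR403a, DESeq2 with its own factors those of miR156a and miR403a, and 1 fit of all treatments that of miR403a. MIR164h lost its call without control replicate 1 (adjusted p = 0.0665) or 3 (0.367). MIR161 lost it without any 1 of the libraries (0.299, 0.190 and 0.368 without control replicates 1 to 3, and 0.0551, 0.108 and 0.0520 without DTT replicates 1 to 3). MIR163 lost it without control replicate 1 (0.299), 2 (0.179) or 3 (0.595) or DTT replicate 2 (0.195), and miR156a without control replicate 1 (0.236), 2 (0.190) or 3 (0.595) or DTT replicate 1 (0.0794) or 2 (0.354). The miR403a call held only without control replicate 2, with 0.236 and 0.612 without control replicates 1 and 3 and 0.131, 0.108 and 0.0871 without DTT replicates 1 to 3.

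Several signals had large differences between DTT and control that did not pass the test. The signal of ath-miR5634 (5DL) was at 1.61 ± 2.14 in the control and 10.02 ± 4.42 in DTT (log2 2.54, SE 0.88, adjusted p = 0.0902). That of osa-miR167d-5p_L-3R+1 (5BL) was at 16.5 ± 8.72 and 4.74 ± 2.77 (log2 -1.78, SE 0.61, adjusted p = 0.0902). For aof-miR166b_L-2 (1AL, 1BL, 1DL) the values were 8.94 ± 2.59 and 2.12 ± 2.01, and for atr-MIR397a-p3_2ss15AT18GT (5AL, 5BL, 5DL) 9.62 ± 1.41 and 2.38 ± 2.11, both with an adjusted p of 0.194. The signal of ath-miR847_L-2 on 1DS stood at 130.5 ± 20.5 and 70.9 ± 21.9. A signal of tae-miR160 (2BL) stood at 14.5 ± 10.7 and 5.31 ± 5.33 (adjusted p = 0.196).

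By conserved family, 63 members were tested between DTT and control (61 distinct signals, since 2 tae-miR159a_R-1 signals stand in the lists of both miR159 and miR319), of which 2 were higher and 0 lower over all signals, the miR156a and MIR164h signals named above, with 3 higher and 3 lower adjusted over the list alone. The latter were 1 signal each of miR156, miR164 and miR395 (higher) and of miR167, miR168 and miR397 (lower). The lists of miR395, miR168 and miR397 had 1 tested member each, so their p-values stood unadjusted, and no adjustment was made over the lists. Summed over all signals of a family, miR167, which targets auxin response factors, was at 159.9 ± 13.6 in the control and 89.9 ± 26.1 in DTT (log2 -0.83, SE 0.34, adjusted p = 0.139). The sum of miR398, a family that targets copper/zinc superoxide dismutase, was 8.40 ± 4.35 and 20.1 ± 12.8 (log2 1.23, adjusted p = 0.139). For miR395, which targets ATP sulfurylase and a sulfate transporter, it was 5.85 ± 1.18 and 16.1 ± 9.21 (log2 1.45, adjusted p = 0.139), and for miR164 185.6 ± 12.2 and 292.3 ± 88.6 (log2 0.66, adjusted p = 0.276). The gain of miR164 lay mostly in the zma-MIR164h signal, while tae-miR164 (7AL, 7DL) was at 83.1 ± 15.3 in the control and 74.4 ± 37.6 in DTT. The miR156 sum was at 80.1 ± 9.12 in the control and 79.7 ± 24.7 in DTT (log2 -0.01, adjusted p = 0.979). Its miR156a signal on 6AS and 6DS was at 20.4 ± 3.77 and 13.2 ± 4.20. By edgeR 0 of 23 family sums passed, with 4 at an unadjusted p under 0.05, and other tools were not run on the sums. Under TMM 2 passed, miR164 (log2 0.79, adjusted p = 0.0101) and miR395 (log2 1.56, adjusted p = 0.0408), and the same families passed after median centring (adjusted p = 0.00544 and 0.04996). Without DTT replicate 3 there were 3 higher, miR164 (adjusted p = 0.00126), miR395 (0.0101) and miR398 (0.0101), and 1 lower, miR167 (0.0382). The median of miR167 members, at log2 -1.05, lay at percentile 2.4 of random lists, and the other 6 lists with a percentile lay between 2.5 and 97.5.

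DTT with TUDCA was compared with the control to find signals that change when the chaperone is given along with the reductant. Among the tested signals 14 were higher, 2 lower and 150 not called, and 33 had an unadjusted p under 0.05. Among the stronger signals, that of zma-MIR164h-p5_2ss4CG17CG_1 (6AL) rose from 25.0 ± 4.75 to 96.9 ± 31.9 reads per 10M (log2 1.95, SE 0.35, adjusted p = 2.04e-05), and that of tae-miR9676-5p rose from 66.7 ± 15.4 to 186.8 ± 23.8 (log2 1.49, SE 0.30, adjusted p = 0.000223). The signal of aly-MIR163-p5_2ss8GA18GC (7BS) rose from 45.8 ± 7.98 to 118.0 ± 11.8 (log2 1.36, SE 0.32, adjusted p = 0.000937), that of atr-MIR8606-p5_2ss15TG18AG (1DL) from 2.73 ± 0.828 to 20.9 ± 2.17 (log2 2.87, SE 0.51, adjusted p = 2.04e-05) and that of aly-miR156a-5p_R+1_1ss20CT (3B) from 5.52 ± 0.779 to 24.6 ± 8.75 (log2 2.13, SE 0.46, adjusted p = 0.000425). Both tested miR398 signals rose, ath-miR398b-3p_1ss20TG (2AL) from 4.07 ± 2.04 to 20.1 ± 4.15 (log2 2.25, SE 0.49, adjusted p = 0.000425) and tae-miR398 (2AS, 2BS, 2DS) from 3.80 ± 1.91 to 13.1 ± 4.92 (log2 1.74, SE 0.54, adjusted p = 0.0212). A signal of aly-miR172c-3p_L-3 (6DS) rose from 2.74 ± 1.83 to 15.1 ± 2.47 (log2 2.41, SE 0.55, adjusted p = 0.000883), and miR172 targets AP2-like transcription factors. The signal of ath-miR5634 (5DL) rose from 1.61 ± 2.14 to 12.96 ± 7.02 (log2 2.90, adjusted p = 0.000937). The signal of tae-MIR1135-p3_1ss21TC, spread over 20 transcripts, had 2 reads in the control and 32 in DTT with TUDCA, a ratio of 15.1 (counting interval 3.85 to 129.9, adjusted p = 0.00585). Other gains were those of gma-MIR5368-p5_1ss3TC (6AL, 6DL, log2 1.57), bdi-MIR444b-p3 (7AL, 7DL, log2 1.59), ath-miR847_L-2 on 2BS (log2 2.02) and pab-MIR11418-p3_2ss11GT18TG (4BL, 4DL, log2 1.34), with adjusted p between 0.0110 and 0.0171. The signal of mtr-MIR2592bj-p3_2ss10TC17AT fell from 33.9 ± 9.89 to 15.2 ± 2.80 (log2 -1.16, SE 0.39, adjusted p = 0.0401), and that of har-miR403a_R-3 (2AL, 2BL, 2DL) from 9.31 ± 5.55 to 2.08 ± 0.422 (log2 -2.10, SE 0.71, adjusted p = 0.0421). In each of the 16 the groups did not overlap, as in 38 of all tested signals (22.9%, where chance gives 10%).

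The whole set of signals lay higher with DTT and TUDCA than in the control, with a median log2 fold change of 0.30 by library reads, 0.10 by TMM and 0.01 after median centring. Relative to that 0.30, MIR8606 stood at 2.57, miR5634 at 2.60, miR172c at 2.11, miR398b at 1.95, miR156a at 1.83, MIR164h at 1.64, miR9676-5p at 1.19, MIR163 at 1.06, miR403a at -2.40 and MIR2592bj at -1.46. The split of higher and lower calls was 14 and 2 (87.5% higher), 9 and 2 under TMM (81.8%), and 9 and 4 after centring (69.2%). The 5 gains that ended with both scalings were those of gma-MIR5368-p5_1ss3TC, bdi-MIR444b-p3, ath-miR847_L-2 (2BS), pab-MIR11418-p3_2ss11GT18TG and tae-miR398, and these also ended by both DESeq2 fits, by limma, without a filter on low counts and in 1 fit of all treatments. The same tests ended the lower call of miR403a, and all but DESeq2 with its own factors that of MIR2592bj. With lines merged at 5% the counts were 27 and 2. The calls of 7 signals (MIR8606, miR172c, miR398b, miR156a, MIR164h, miR9676-5p and MIR163) held under every alternative test, scaling, filter and merging rule and without any 1 library. The counts were 16 and 3 without control replicate 1, 11 and 2 without control replicate 2, 11 and 0 without control replicate 3, 22 and 2 without replicate 1 of DTT with TUDCA, 8 and 2 without its replicate 2, and 8 and 0 without its replicate 3. Without control replicate 2, miR172c stood at log2 3.09 (adjusted p = 0.0148), while miR5634 had 1 against 50 reads, a ratio of 31.0 (counting interval 5.32 to 1250), and miR847 on 2BS 2 against 48, a ratio of 14.9 (counting interval 3.90 to 126.5). The miR5634 call was lost without replicate 2 of DTT with TUDCA (adjusted p = 0.126), and that of MIR1135 without its replicate 3 (0.120), by DESeq2 with either scaling, by limma and without a filter on low counts. The calls of MIR5368 (0.0912, 0.171, 0.0620 and 0.0737), MIR444b (0.0912, 0.0766, 0.0694 and 0.251) and tae-miR398 (0.121, 0.171, 0.0829 and 0.303) were each lost without control replicate 2 or 3 or without replicate 2 or 3 of DTT with TUDCA. The miR847 call on 2BS was lost without control replicate 1 (0.0762) or 3 (0.171) or replicate 2 (0.0581) or 3 (0.251) of DTT with TUDCA, and that of MIR11418 without control replicate 1 (0.0707) or 2 (0.129) or replicate 2 (0.248) or 3 (0.108). The lower call of miR403a held only without control replicate 2 (otherwise 0.0858 and 0.422 without control replicates 1 and 3, and 0.0538, 0.129 and 0.251 without the treated replicates 1 to 3). That of MIR2592bj held only without control replicate 1 (otherwise 0.129 and 0.0705 without control replicates 2 and 3, and 0.0593, 0.194 and 0.108 without the treated replicates).

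**Figure D2:**
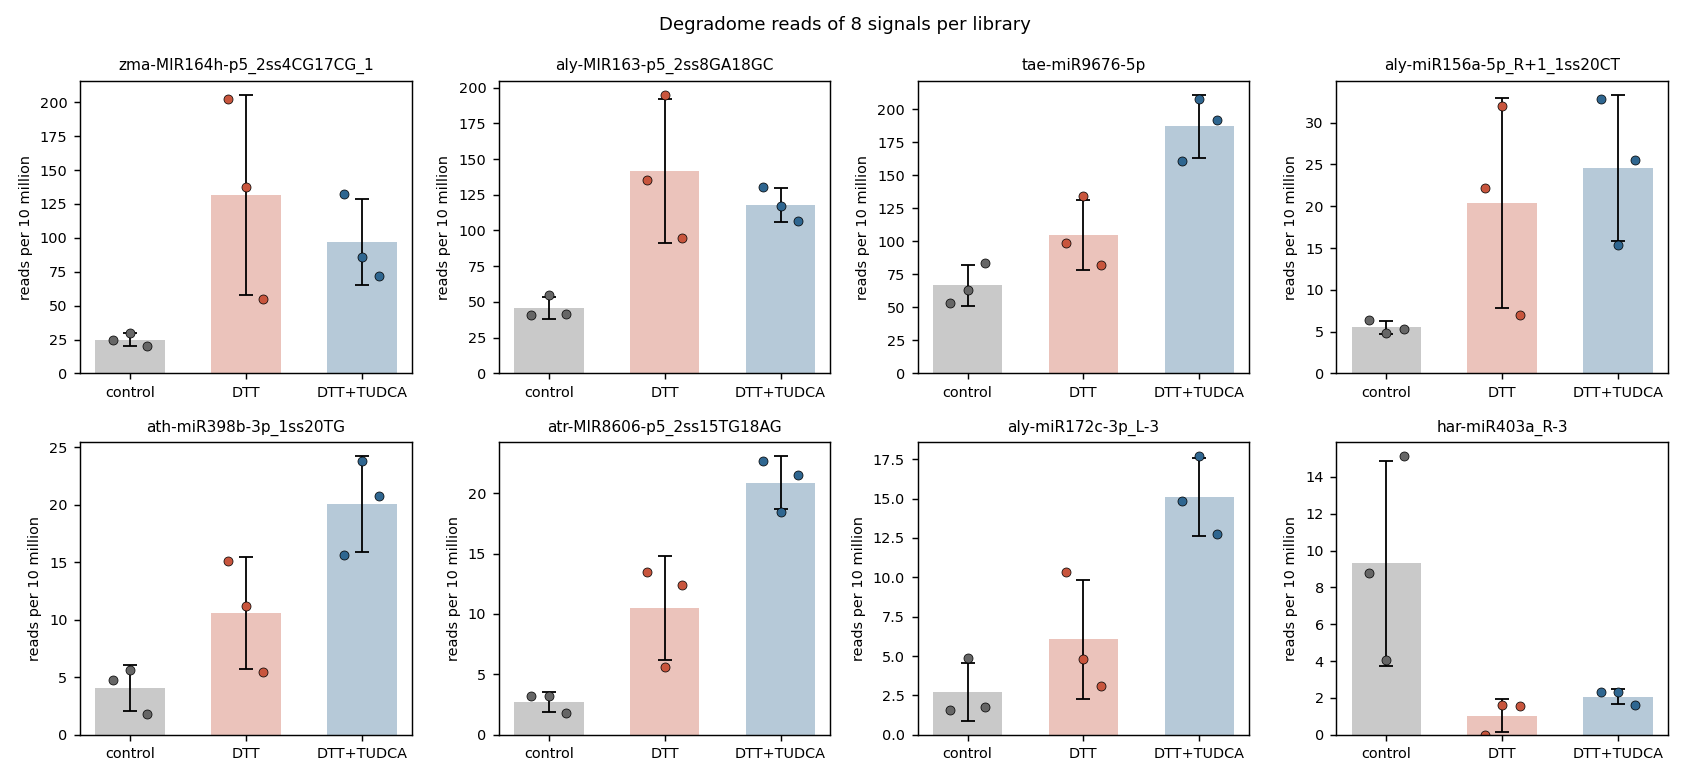
Reads per 10M library reads of 8 signals in each library, where points are libraries and bars are means with SD of 3 libraries, each panel on its own linear axis from 0. The zma-MIR164h signal stands at 25.0 in the control, 131.6 in DTT and 96.9 in DTT with TUDCA, and har-miR403a_R-3 at 9.31, 1.05 and 2.08.

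Of the conserved families, 68 members (66 distinct signals) were tested between DTT with TUDCA and control, with 6 higher and 0 lower over all signals and 9 higher and 2 lower adjusted over the list alone. The higher ones over all were 2 of 2 tested members of miR398, and 1 each of miR156 (4 tested), miR164 (6), miR172 (10) and miR444 (1). Adjusted over the list alone, 3 members of miR396, which targets growth-regulating factors, were added, of which ata-miR396c-5p and pab-miR396b hold identical counts and are probably the same reads, and 1 member each of miR168 and miR394 was lower. The lists of miR168 and miR394 had 1 tested member each, so their p-values stood unadjusted. The summed miR398 signals rose from 8.40 ± 4.35 to 33.9 ± 8.41 reads per 10M (log2 1.98, SE 0.39, adjusted p = 0.0104), those of miR164 from 185.6 ± 12.2 to 296.1 ± 12.7 (log2 0.67, SE 0.12, adjusted p = 0.0104) and those of miR444, which targets MADS-box transcripts, from 20.4 ± 1.61 to 37.5 ± 1.45 (log2 0.87, SE 0.18, adjusted p = 0.0104). Relative to the median of all signals these were 1.68, 0.37 and 0.57. The sums of miR156 (80.1 ± 9.12 to 111.3 ± 3.30), miR169 (333.2 ± 53.4 to 464.2 ± 34.0), miR395 (5.85 ± 1.18 to 16.9 ± 8.39) and miR1432 (2 against 16 reads, a ratio of 7.54 with a counting interval of 1.77 to 67.6) passed with an adjusted p of 0.0438. The gain of miR164 lay mostly in the zma-MIR164h signal, while tae-miR164 (7AL, 7DL) was at 83.1 ± 15.3 and 89.1 ± 12.3. That of miR444 lay mostly in the bdi-MIR444b-p3 signal (7AL, 7DL), at 6.36 ± 0.858 and 19.3 ± 8.57. The call of this signal by itself ended under TMM and centring. Thus 7 of 24 sums were higher and 0 lower by edgeR, with 9 at an unadjusted p under 0.05, and other tools were not run on the sums. Under TMM miR164, miR169, miR398, miR444 and miR1432 stayed higher, and after centring miR398 and miR1432, while miR171 (log2 -0.93 and -1.02) and miR397 (log2 -1.09 and -1.18) passed as lower under both. With all 3 treatments in 1 fit, and with every listed line, miR398 alone kept its call. The counts of sums were 2 and 0 without control replicate 1, 6 and 1 without 2, 3 and 0 without 3, and 6 and 0, 3 and 1, and 2 and 0 without the treated replicates 1, 2 and 3. Of the libraries left out, only treated replicate 3 ended the miR398 call (adjusted p = 0.0600), only control replicate 1 that of miR444 (0.0746), and none that of miR164. The miR156 and miR169 calls held only without control replicate 2. Without control replicates 1 and 3 and treated replicates 1 to 3, adjusted p was 0.0993, 0.123, 0.0628, 0.108 and 0.1004 for miR156 and 0.0993, 0.123, 0.0673, 0.108 and 0.147 for miR169. The miR395 and miR1432 calls held only without treated replicate 1. Without control replicates 1 to 3 and treated replicates 2 and 3, adjusted p was 0.0993, 0.0922, 0.123, 0.142 and 0.1004 for miR395 and 0.0993, 0.0597, 0.0856, 0.142 and 0.1004 for miR1432. The medians of all 9 lists with a percentile lay between 2.5 and 97.5 of random lists.

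**Figure D3:**
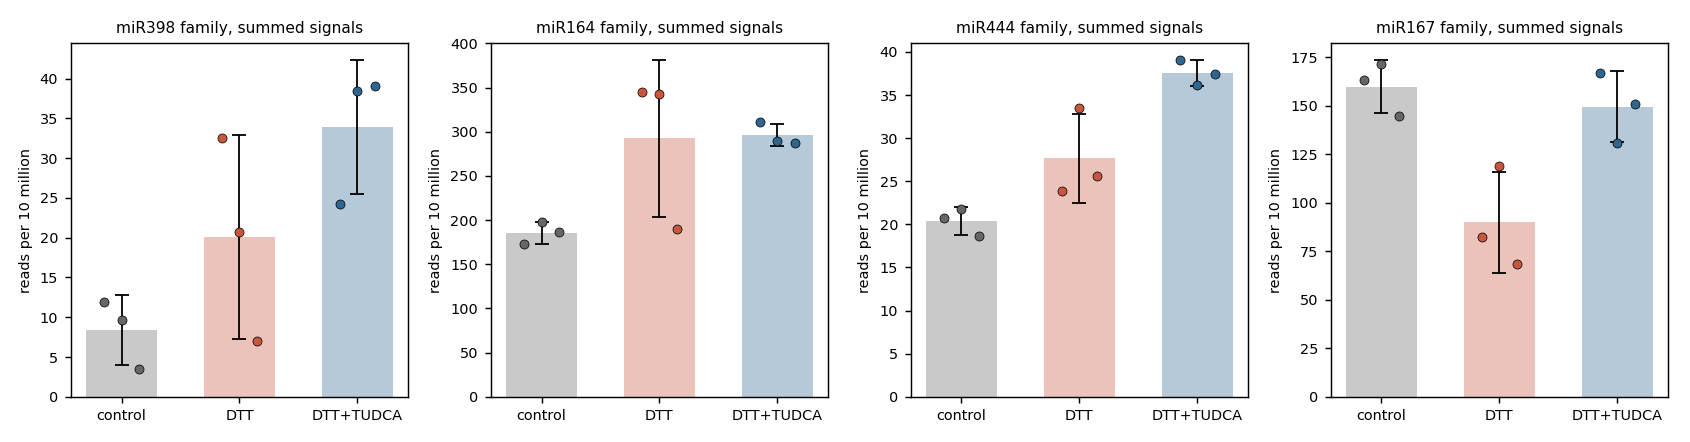
Summed reads per 10M library reads of all signals of the miR398, miR164, miR444 and miR167 families in each library, where points are libraries and bars are means with SD of 3 libraries, on linear axes from 0. Summed miR398 signals stand at 8.40 in the control, 20.1 in DTT and 33.9 in DTT with TUDCA, and those of miR167 at 159.9, 89.9 and 149.5.

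DTT with TUDCA was compared with DTT alone to find signals that change when the chaperone is added to the reductant. The signal of osa-MIR156k-p3_2ss13TC17TC (6DS) rose from 1 read in the 3 DTT libraries to 37 with TUDCA, a ratio of 36.7 (counting interval 6.19 to 1487.1, adjusted p = 0.0190), and stood at 4.46 ± 2.55 reads per 10M in the control. The signal of osa-miR5071_1ss15GA (1BL) rose from 2.37 ± 0.0364 to 14.6 ± 6.002 (log2 2.58, SE 0.60, adjusted p = 0.0390), and stood at 8.59 ± 4.09 in the control. In both signals the groups did not overlap, as in 29 of 187 tested signals (15.5%, where chance gives 10%). None of the 4 signals that rose in DTT passed here. MIR164h was at 131.6 ± 73.9 and 96.9 ± 31.9 (log2 -0.44, SE 0.49, adjusted p = 0.836), MIR161 at 30.3 ± 2.79 and 20.3 ± 0.370 (log2 -0.57, SE 0.40, adjusted p = 0.752), MIR163 at 141.5 ± 50.4 and 118.0 ± 11.8 (log2 -0.26, SE 0.44, adjusted p = 0.938) and miR156a at 20.4 ± 12.6 and 24.6 ± 8.75 (log2 0.27, SE 0.50, adjusted p = 0.938). By edgeR 2 signals were higher and 0 lower, with 13 at an unadjusted p under 0.05. The count of lower signals was also 0 by DESeq2 and limma, and the higher ones were 1 by DESeq2 with library reads, 0 by DESeq2 with its own factors, 1 by limma, and 2 with lines merged at 5%. The median log2 fold change of all signals was 0.26 by library reads, -0.02 by TMM and -0.09 after centring, and relative to 0.26 miR5071 stood at 2.32. The count of higher signals was 0 without DTT replicate 3 or replicate 3 of DTT with TUDCA and 1 without any other library. Without DTT replicate 1, which holds its only DTT read, MIR156k had 0 against 37 reads, a ratio of 8.17 to a floor of 3 counts (adjusted p = 0.0258). It lost its call without DTT replicate 3 (adjusted p = 0.127) or replicate 1 (0.0944) or 3 (0.541) of DTT with TUDCA, and by DESeq2 with its own factors. The miR5071 call ended under TMM and centring, by both DESeq2 fits and limma, without a filter on low counts and with every listed line. With a library left out it held only without replicate 1 of DTT with TUDCA (otherwise 0.106, 0.0753 and 0.186 without DTT replicates 1 to 3, and 0.299 and 0.541 without replicates 2 and 3 of DTT with TUDCA).

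Other large differences between DTT with TUDCA and DTT did not pass. They included pab-MIR11418-p3_2ss11GT18TG (4BL, 4DL) at 9.50 ± 2.97 and 32.5 ± 13.4 (log2 1.77, SE 0.47, adjusted p = 0.0856) and osa-miR167d-5p_L-4R+1 (5BL) at 6.84 ± 0.555 and 19.3 ± 2.56 (log2 1.48, SE 0.46, adjusted p = 0.222). The signal of ath-miR847_L-2 on 1DS was at 70.9 ± 21.9 and 145.0 ± 17.7 (log2 1.03, adjusted p = 0.626), and gma-miR6300_L-1R+1 (2AL, 2BL) at 32.4 ± 20.3 and 13.8 ± 0.539 (log2 -1.23, adjusted p = 0.561). Of 73 members of conserved families (72 distinct signals), 1 was higher and 0 lower over all signals, and 2 were higher and 0 lower adjusted over the list alone, of miR156 and miR167. The summed miR167 signals were at 89.9 ± 26.1 and 149.5 ± 18.2 (log2 0.73, SE 0.37, adjusted p = 0.696) and those of miR398 at 20.1 ± 12.8 and 33.9 ± 8.41 (log2 0.75, adjusted p = 0.696). By edgeR 0 of 24 sums passed, with 0 at an unadjusted p under 0.05, and none passed under TMM or centring. The member medians of miR156 (percentile 98.5) and miR167 (98.6) lay above the central 95% of random lists and that of miR393 (percentile 2.1) below it, and the other 6 lists lay within.

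Of the signals called against the control, 3 were higher in both DTT and DTT with TUDCA (MIR164h, MIR163 and miR156a) and 1 was lower in both (miR403a), of 138 tested in both. Independent lists would share 0.406 higher and 0.0145 lower signals. The lists share their control libraries, however, and no expected overlap that allows for this was computed. Over 221 signals the log2 fold changes of the 2 comparisons had a correlation across signals of 0.73 and a covariance of 0.726, against 0.50 and 0.210 in 100 simulations of unchanged groups set against the same controls, a difference in covariance of 0.516. The simulated ranges were 0.38 to 0.62 and 0.132 to 0.298. The share with the same sign was 72.9%, inside the simulated range of 56.6% to 75.1%. The 3 control libraries are too few to be split, so part of the excess may come from sharing them. Between DTT against control and DTT with TUDCA against DTT, which share the DTT libraries, the correlation was -0.35 and the covariance -0.254, against -0.50 (range -0.60 to -0.37) and -0.207 (range -0.302 to -0.14) simulated. Signals are not independent replicates.

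The authors' deposited tables gave a direction to every listed pair of small RNA and transcript: 4440 up and 5211 down in DTT against control, 5655 and 4920 in DTT with TUDCA against control, and 5965 and 4410 in DTT with TUDCA against DTT. In these tables, 58.9%, 61.2% and 59.2% of the lines had no ratio, because 1 treatment had no reads, and 60.5%, 63.1% and 60.4% rested on 3 reads or fewer. The tables list 3592, 3814 and 3857 signals, of which 476, 502 and 537 had at least 10 reads, on 5824, 6365 and 6241 transcripts for 1133, 1169 and 1165 small RNAs. All 3 tables share 2115 signals (46.2%). With 1 added to each mean in reads scaled to the mean library size, 259 signals were at least 2-fold higher and 258 lower in DTT than in control, 302 and 246 in DTT with TUDCA than in control, and 229 and 200 in DTT with TUDCA than in DTT. After median centring the counts were 251 and 292, 172 and 607, and 197 and 353. Without control replicate 1 the lower counts against the control were 431 and 413. With 5 added, the counts were 13 and 6, 28 and 3, and 8 and 1. With 1 added, the largest decrease between DTT with TUDCA and control was that of PC-3p-177130_11 (log2 -2.72). This ranking took signals with a larger mean of at least 10 in reads scaled to the mean library size. The signal had 34 reads in the control, but did not pass the expression filter in that comparison and was not tested there.

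No table used here names the transcripts, so their identities are given only as chromosome arms. The signal of zma-MIR164h lay on Traes_6AL_2E1CB2A66 and that of atr-MIR8606 on Traes_1DL_88D2ACD05, both of which rose, and the signal of har-miR403a_R-3, which fell, was led by Traes_2AL_264BF03F4.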

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

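The tests under TMM, DESeq2, limma, other filters, other merging rules, 1 fit of all treatments, the replicate block and all tests of family sums were chosen after seeing the data, while median centring, 1 line per transcript, the added read numbers and leaving out each library were planned. In the main setting 4 signals were higher and 1 lower in DTT than in control, 14 and 2 in DTT with TUDCA than in control, and 2 and 0 in DTT with TUDCA than in DTT. No call against DTT or of DTT against control held under every alternative and every library left out, and 7 of 16 held for DTT with TUDCA against control. Depth limits which signals could be tested, since 61.6% have 3 reads or fewer and did not enter the main test of single signals, and replicates differed beyond counting error (chi-square per degree of freedom 1.55 to 4.99). Planned comparisons by cleavage category, alignment score, position within 1 nt, deposited p-values, small RNA abundance and its direction against the targets were not run, because the tables hold none of these. For changes with an alternative the cause was not tested, except where fewer signals or libraries entered the fit.

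In the order DTT against control, DTT with TUDCA against control, and DTT with TUDCA against DTT, the higher and lower counts were 3 and 0, 9 and 4, and 1 and 0 after median centring, and 4 and 0, 9 and 2, and 1 and 0 under TMM. They were 2 and 0, 8 and 0, and 1 and 0 by DESeq2 with library reads, 3 and 0, 8 and 2, and 0 and 0 by DESeq2 with its own factors, and 0 and 0, 10 and 0, and 1 and 0 by limma. Without a filter on low counts they were 1 and 0, 8 and 1, and 1 and 0, with edgeR's default filter 3 and 0, 14 and 1, and 0 and 0, and with all 3 treatments in 1 fit 4 and 0, 10 and 1, and 3 and 0. With 1 line per transcript they were 1 and 0, 37 and 13, and 2 and 0, with merging at 5% 6 and 1, 27 and 2, and 2 and 0, with merging of identical counts only 5 and 1, 29 and 2, and 2 and 0, and with every listed line 2 and 0, 74 and 12, and 1 and 0. These settings count some reads more than once. With each library left out in turn, the higher counts ranged from 0 to 3, 8 to 22, and 0 to 1, and the lower counts from 0 to 3, 0 to 3, and 0 to 0.

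With replicate number as a block the counts were 1 and 0, 17 and 1, and 1 and 0, and 3 family sums were higher in DTT with TUDCA than in control instead of 7. Pairing of the samples by number was not evident. Same-numbered libraries deviated with correlations from -0.078 to 0.015, 0.056 to 0.117, and -0.23 to -0.042 in the 3 comparisons. Not every library correlated best with its own number, although replicates 1 and 3 did in DTT with TUDCA against control. With 3 libraries per treatment, pairing is not excluded.

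Family sums in DTT against control, 0 higher and 0 lower in the main setting, were 2 and 0 after median centring and under TMM, 0 and 1 with merging at 5% and of identical counts only, and ranged from 0 to 3 higher and 0 to 1 lower with each library left out. In DTT with TUDCA against control, 7 and 0 became 2 and 2 after centring, 5 and 2 under TMM, 1 and 0 with all treatments in 1 fit, 7 and 1 with merging at 5% and of identical counts only, and 1 and 0 with every listed line. Leaving out libraries gave 2 to 6 higher and 0 to 1 lower. Between DTT with TUDCA and DTT all settings gave 0 and 0.

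Listed signals at least 2-fold higher and lower numbered 259 and 258, 302 and 246, and 229 and 200 in the 3 comparisons with 1 added to each mean in reads scaled to the mean library size. They numbered 13 and 6, 28 and 3, and 8 and 1 with 5 added, 1490 and 1267, 1726 and 1183, and 1609 and 1260 with 0.1 added, and 14 and 10, 23 and 6, and 9 and 2 where the larger value was at least 10. After median centring the count in DTT with TUDCA against control was 172 and 607, and 353 were lower against DTT. With 1 line per transcript 429, 487 and 348 were higher and 307 were lower in DTT with TUDCA than in DTT. With each library left out the higher counts ranged from 287 to 348, 327 to 359, and 243 to 328, and the lower from 279 to 431, 273 to 413, and 217 to 266. The median log2 ratio of listed signals was 0.08, 0.31 and 0.17, with left-out ranges from -0.31 to 0.40, 0.13 to 0.40, and -0.01 to 0.40, and was 0.65 for DTT with TUDCA against control with 0.1 added. With at least 10 reads the listed signals numbered 476, 502 and 537 of 3592, 3814 and 3857, the transcripts 789, 823 and 864, and the small RNAs 475, 480 and 471.

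The 1134 values of named signals under alternatives include signals not called in the main setting, which keep their side of the threshold by staying uncalled. The share kept is therefore not the share of calls that held. Of the 1134 values, 972 kept direction and side of the threshold, 150 lost the call, 10 gained one and 2 turned. Both turned between DTT with TUDCA and DTT without DTT replicate 1, where aly-miR393b-3p_L-3 went from log2 -0.47 to 0.0113 (range with a library left out -0.88 to 0.0113) and zma-MIR164h-p5_2ss4CG17CG_1 from -0.44 to 0.0108 (range -0.81 to 0.0108), and neither was called in either setting.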

Other observations

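The tests of causes in this part were all chosen only after the result was seen. Of 5245 transcripts with a chromosome arm in the ID, 1750 lay on wheat subgenome A, 1748 on B and 1747 on D (33.4%, 33.3% and 33.3%), where homeologous transcripts can hold the same reads. Of 707 signals with at least 10 reads, 136 had no arm, 303 lay on 1 subgenome, 135 on 2 and 133 on all 3, as did tae-miR160 (1AL, 1BL, 1DL) and har-miR403a_R-3 (2AL, 2BL, 2DL). In 119 of these 133 the arms belonged to 1 chromosome group. Signals of conserved families were called about as often as others in DTT with TUDCA against control, 6 of 66 (9.1%) and 10 of 100 (10%, Fisher exact p = 1.0). The shares were 2 of 61 and 3 of 95 in DTT against control and 1 of 72 and 1 of 115 in DTT with TUDCA against DTT, with Fisher exact p = 1.0 for both.

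The summed miR166 signals, of a family that targets HD-ZIP III transcripts, were at 77.2 ± 6.38 reads per 10M in the control, 71.7 ± 20.2 in DTT and 77.5 ± 15.8 in DTT with TUDCA, and those of miR172 at 257.3 ± 39.6, 222.5 ± 53.8 and 279.1 ± 35.5. The signal of aly-miR172c-3p on 2AL was at 77.3 ± 23.3, 81.6 ± 33.4 and 95.5 ± 14.0, and that on 1AS at 81.7 ± 13.3, 47.0 ± 24.6 and 71.5 ± 21.5. The summed miR168 signals, of a family that targets AGO1, were at 61.7 ± 20.7, 35.6 ± 14.2 and 35.1 ± 14.3, which did not pass in either treatment (adjusted p = 0.217 and 0.120).

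More signals were detected, and more were called higher, in DTT with TUDCA than in the control. Depth in library reads is argued against, since at the depth of the smallest library the lowest library of DTT with TUDCA still had 141.7 signals more than the highest control library. Depth in mapped reads was not tested, as it is not known whether the library reads are mapped reads. A single factor on every signal as the whole cause of the 14 higher signals, among them zma-MIR164h, ath-miR398b-3p and tae-miR398, is not decided by their median. Their median log2 fold change was 1.98 (SE 0.473) before and 1.72 (SE 0.473) after centring, with the lowest at 2.53 times its SE. These signals were picked by the test before centring, so their median after it was bound to stay high. Over all tested signals centring took the median from 0.30 to 0.01, and the calls after it were 9 higher and 4 lower. The 9 higher were all among the 14, with a centred median of 1.96 (SE 0.483). Their adjusted p, taken over all tested signals, was at most 0.0167 under TMM and centring. This argues against a single factor as the whole cause for these 9 only. For 5 of the 14, among them tae-miR398, the median went from 1.59 (SE 0.459) to 1.28 (SE 0.46), and the call ended with the fold lower at a similar SE, with adjusted p up to 0.113. Of the 10 splits of the 6 libraries, 1, the real one, gave as many calls in each comparison (5, 16 and 2 called, and at most 1, 0 and 1 in another split), and 10 splits cannot give a share under 0.05.

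Of the 4 signals called higher in DTT, 3 (zma-MIR164h, aly-MIR163 and aly-miR156a) were also called higher with TUDCA present. The other, aly-MIR161 (5BL), was not called there by edgeR (log2 1.10, SE 0.42, adjusted p = 0.0878). The covariance between the 2 sets of log2 fold changes against the control was 0.726, where the spread of the control mean gives 0.231. The excess was 0.494 (bootstrap SE 0.0791). That SE is over signals from the same 9 libraries, so it leaves out the error of 3 libraries per treatment. The covariance lay above its simulated range of 0.132 to 0.298. The share with the same sign, 72.9%, lay inside the simulated range of 56.6% to 75.1%. Noise of the shared control libraries is therefore not excluded. With TUDCA, log2 fold changes against the control were 1.95 (SE 0.35) for MIR164h, 1.36 (SE 0.32) for MIR163 and 2.13 (SE 0.46) for miR156a. Measured against these control libraries, this argues against a full return to the control level for these 3 signals. For MIR161 a full return stays open. A part return stays open, since the covariance of the DTT change with the change on adding TUDCA exceeded that from the shared DTT libraries by 0.0269 (SE 0.055). As a hypothesis, the 3 signals higher in both may follow DTT whether or not TUDCA is given, but a difference of the control set as a whole from both treated sets, in growth or handling, cannot be separated from it.

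DTT replicate 3 had the fewest reads in signals, 3699.8 per 10M. Fewer library reads are argued against as the cause, at 12.9M reads against 12.6 and 12.53 in the other DTT libraries. Whether these are raw, filtered or mapped reads is not known, so a lower depth in mapped reads stays open. A single factor on all its signals stays open, since after scaling to equal totals its pairs with the other replicates had a chi-square per degree of freedom of 4.52 on average (4.99 and 4.04), against 4.41 for the pair without it. No biological explanation was tested for this library.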
